A study of Mus musculus with 38 samples.

How the data were processed

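Testis RNA of LuRKO mice and wild-type littermates was measured on 38 single-colour Illumina bead arrays, each of RNA pooled from 2 animals. Per the labels' protocols, RNA was extracted with TRI reagent and a column kit, amplified to biotin-labelled cRNA and read with BeadStudio, whose version is not given in the sources used here. The deposited values used here are probe intensities on a linear scale that the authors had already normalized by quantiles, and array medians lay between 108.1 and 108.3. A second table of non-normalized signals was not used, because its 76 per-array columns match no label. The design fixed before the data were examined had assumed these signals and their detection p-values, so the background correction, the detection rule and the first other setting below differ from it.

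Background was corrected with normexp (offset 50) on the normalized intensities, in limma 3.58.1 under R 4.3.3, followed by log2. The background level was taken as the mode of the intensities, 75.9, and the threshold for above background was 102 (6.62 on the corrected log2 scale), from the spread below the mode at a one-sided 0.01. Of 45281 probes 34885 had 1 gene symbol, 18 had several and 10378 had none listed, and symbols were updated from RefSeq gene tables of GRCm38.p6. A probe was kept if above background on at least 2 arrays, which left 31872 probes, 25840 of them with 1 symbol. The probe with the highest mean stood for its gene, giving 15194 genes, of which 6671 had more than 1 kept probe. A gene not above background on any array of 1 group has a fold written as at least N-fold, set against the mean of, per array, the higher of the threshold and its own signal. Between 24067 and 24103 probes were above background on each array.

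Groups were taken from the labels. A model with 1 mean per group was fitted to all 38 arrays with limma's lmFit and eBayes (18 residual and 10.4 prior degrees of freedom), so that groups of 1 array borrow the spread of the others. Comparisons were LuRKO against wild type at each age, averaged over ages, and as an interaction with age; day 27 against day 3; each time after testosterone against untreated day 19 LuRKO testes; each dose against vehicle, with a slope from 250 ng to 25 µg; and 48 h against vehicle for the rescue. P-values were adjusted by Benjamini and Hochberg and called under 0.05. The 21 gene lists, fixed before the data were examined together with the comparisons, the other settings to try and the rule for named genes, were steroidogenesis; adult Leydig cell markers; fetal and immature Leydig or interstitial stem cell markers; Sertoli cell markers; androgen-responsive Sertoli cell genes; spermatogonial markers; meiotic prophase genes; spermatid genes; peritubular myoid and smooth muscle markers; macrophage markers; endothelial markers; erythroid genes; epididymal and efferent duct markers; cholesterol biosynthesis and uptake; vitamin A metabolism and signalling; immediate early genes; glucocorticoid and androgen receptor shared targets; circadian clock genes; cell cycle genes; tight junction genes; and fibrillar and basement membrane matrix. They hold 365 genes, of which 364 matched a current symbol, 3 of these through a synonym, and 301 were tested, with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. Of the 77 list tests called, 14 were called with an estimated correlation.

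Named genes were, for each genotype, time and dose comparison, the 3 largest increases and 3 largest decreases among called genes with every array on the same side of every control array. For development and the rescue they were the 5 largest each way, for the interaction and slope the 3 smallest p-values, and for each list up to 4 called members or the member with the largest change, besides a fixed panel of testis genes. A gene named in 1 comparison is also given in others, and not every gene the rule allows is printed.

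On simulated arrays with 200 of 15194 genes changed, the day 19 genotype comparison called 34 of 67 genes changed by 0.5 (log2), 66 of 67 changed by 1 and 66 of 66 changed by 2, with 3 false calls. The comparison of 2.5 mg with vehicle, 1 array against 2, called 11 of 67, 64 of 67 and 66 of 66, with 8 false calls. Simulated noise was independent between genes and arrays, with the fitted spread, and the changed genes lay above background in every group. Outlying arrays and differences between sets of arrays were not simulated, so false calls from these are not counted. The other settings fixed beforehand were the authors' values without further background correction, scaling to 1 median, other control groups, other detection filters, the mean of a gene's probes, a replicate block, arrays of 1 series alone, 24 h in place of 48 h and leaving out each array. An offset of 16, the 2 h group and the 4 low-dose arrays as controls, days 8, 13 and 19 alone, and leaving out 3 doubted arrays were added after the data were seen.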

Results

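RNA from mouse testes was measured on 38 single-colour Illumina bead arrays in 20 groups. LuRKO mice lack a functional receptor for luteinizing hormone, the pituitary hormone that drives testosterone synthesis in Leydig cells. The first set of arrays followed LuRKO mice and their wild-type littermates at days 3, 8, 13, 19 and 27, with birth as day 1. The second set followed LuRKO testes after a single injection of 2.5 mg testosterone propionate at day 19, with samples after 2, 4, 8 and 12 h and after 1 and 2 days (24 and 48 h). The third set compared vehicle, 250 ng, 2.5 µg, 25 µg and 2.5 mg of the same ester at 24 h. There were 2 arrays in 18 groups and 1 array in 2 groups, LuRKO at day 27 and 2.5 mg at 24 h. Each array held RNA pooled from the testes of 2 animals, so the p-values measure the spread between arrays. Between 24067 and 24103 of 45281 probes were above background on each array. These near-equal numbers follow from the authors' normalization by quantiles and do not measure the quality of the arrays. The number of arrays limits the precision. Values are log2 intensities, differences are given with their standard error (SE), and calls are adjusted p-values under 0.05 from limma over 15194 genes. The genes for the receptors of luteinizing hormone and of androgen were not analysed here. All values are of whole testes, so a change in the share of a cell type cannot be told apart from a change within its cells.

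The series over age first describes how the wild-type testis changed. Genes of spermatids, the haploid germ cells, and of meiosis rose from day 3 to day 27 in wild-type testes (2 arrays against 2). All 30 spermatid genes tested rose, also when adjusted over the list alone, with a median log2 change of 6.33. Of 25 meiotic prophase genes 24 rose and 1 fell, the same counts as adjusted over the list alone. Gtsf1l rose at least 229-fold, Adam3, a sperm membrane protein gene, at least 233-fold, and Hils1, a spermatid linker histone gene, at least 158-fold. Ldhc, the lactate dehydrogenase of germ cells, rose by 6.11 (SE 0.40) on the log2 scale, and by 7.57 without wild-type day 3 replicate A, where it was at 10.61 with 7.70 in replicate B. All 16 fibrillar and basement membrane matrix genes tested fell, also adjusted over the list alone, as did 15 of 17 Sertoli cell markers, with 1 higher. Amh, the hormone of immature Sertoli cells, fell by 4.54 (SE 0.17), and Igfbp5, an insulin-like growth factor binding protein gene, fell by 5.71 (SE 0.17). Of 10 markers of fetal and immature Leydig or interstitial stem cells 9 fell, and among them Thbs2, an extracellular matrix protein gene, fell by 4.41 (SE 0.17). Endothelial markers fell in 9 of 12 cases and peritubular myoid and smooth muscle markers in 8 of 9, with 1 higher, and these counts were the same adjusted over the list alone. By limma's camera, spermatid (adjusted p = 3.9e-20), meiotic (2.3e-12), matrix (7.1e-07) and Sertoli cell lists (1.6e-04) moved beyond other genes. With an estimated correlation the adjusted p-values were 0.016, 0.0017, 0.039 and 0.016, and those of the interstitial, endothelial and myoid lists were 0.072, 0.21 and 0.21. In total 4363 genes were called higher and 6734 lower in wild-type testes, and 4143 higher and 4871 lower in LuRKO testes, where day 27 was 1 array.

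**Figure D1:**
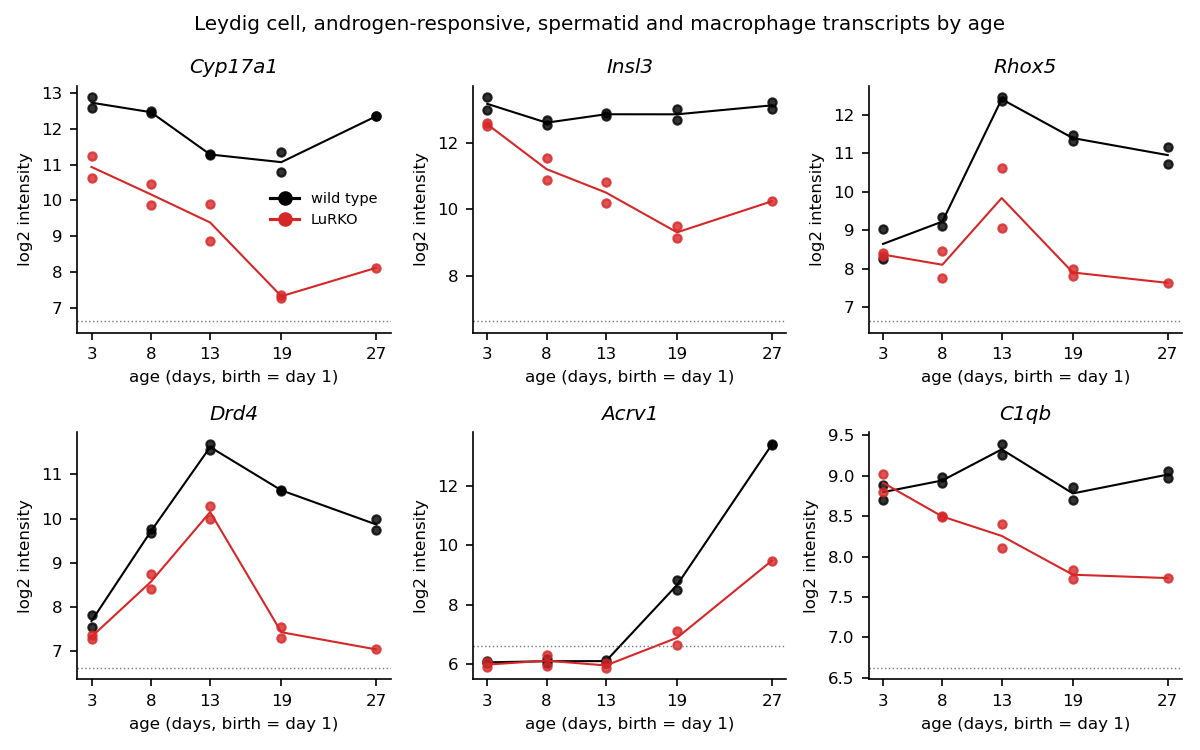
Log2 intensity (y axes) of 6 transcripts by age in days (x axes) in wild-type (black) and LuRKO (red) testes, where points are arrays, lines join group means and the dotted line is the background threshold. Cyp17a1 at day 19 averaged 7.32 in LuRKO and 11.07 in wild-type testes.

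The comparison of genotypes at each age asks when loss of the receptor changes the transcripts of the testis. At day 3, Cyp17a1, the enzyme that makes androgen precursors, was 3.47-fold lower in LuRKO testes (log2 -1.79, SE 0.52, 2 arrays against 2, limma adjusted p = 0.027). Hsd3b1, another steroidogenic enzyme, was 3.03-fold lower (log2 -1.60, SE 0.18). Insl3, a Leydig cell hormone needed for testicular descent, differed by -0.62 (SE 0.46) and was not called. Hspa5, an endoplasmic reticulum chaperone, was lower by -2.12 (SE 0.14), and Prm1, the gene of a sperm protamine, was higher by 1.34 (SE 0.17). Of 25 meiotic prophase genes 7 were lower and none higher, also adjusted over the list alone, with camera adjusted p = 0.0024 and adjusted p = 0.20 with an estimated correlation. Wild-type replicate A had Ldhc at 10.61 where replicate B had 7.70. Without it and 2 other arrays doubted after the data were seen, 4 meiotic genes were lower and 2 higher, 8 and 2 adjusted over the list alone, and camera did not call the list (adjusted p = 0.16). Of 21 spermatogonial markers 4 were lower, 5 adjusted over the list alone (camera adjusted p = 0.043, adjusted p = 0.61 with an estimated correlation). Without the doubted arrays, which left only wild-type replicate B of day 3, these markers had a median of -0.62. Wild-type replicate A was doubted for Ldhc, a germ cell gene, so leaving it out cannot test lists of germ cell genes. Cyp17a1 was not called with an offset of 16 (-1.81, limma adjusted p = 0.075), nor without LuRKO replicate A (log2 -1.50) or B (-2.09), or without wild-type replicate A (-1.64) or B (-1.95), and was called without the 3 doubted arrays together (-1.64). In all 440 genes were higher and 803 lower at day 3, and 708 were called without LuRKO replicate A. Of the 197 genes at least 2-fold lower at day 3, 153 were also at least 2-fold lower in LuRKO testes 2 h after testosterone than in untreated LuRKO testes of day 19. For 51 of the genes lower at 2 h, 65 other probes with a mean log2 over 8 had a median of -0.14 there. The probes used for those genes had -1.37. Lower calls at day 3 may thus partly be of single probes, and Hspa5 has 1 kept probe.

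At day 8 the 7 genes called were all lower in LuRKO testes. Eppin, an androgen-regulated protease inhibitor gene, was lower by -0.93 (SE 0.18, 2 arrays against 2, limma adjusted p = 0.037). Kcnk3, a potassium channel gene, was lower by -1.12 (SE 0.20), and Stard10, a lipid transfer protein gene, by -0.76 (SE 0.14). Cyp17a1 and Insl3 had differences of -2.29 (SE 0.52, adjusted p = 0.11) and -1.40 (SE 0.46, adjusted p = 0.35) and were not called by limma. With only the arrays of the same series both were called (limma adjusted p = 5.2e-05 and 0.0031). Of 14 androgen-responsive Sertoli cell genes 1 was lower, 3 adjusted over the list alone, with camera adjusted p = 0.0014 and adjusted p = 0.25 with an estimated correlation. At an unadjusted p under 0.05 there were 1268 genes by limma. The 7 calls became 0 without LuRKO replicate A, wild-type replicate A or wild-type replicate B of day 8, and 1 without LuRKO replicate B. Without each of these 4 arrays in turn Eppin lay between -1.03 and -0.84, Kcnk3 between -1.27 and -0.97 and Stard10 between -0.84 and -0.68, none of them called. With the mean of each gene's probes Eppin (-0.78) and Stard10 (-0.32) were not called, and another Stard10 probe had 0.11 (SE 0.21). With arrays scaled to 1 median none of these 3 genes was called (limma adjusted p = 0.053 each), nor with an offset of 16 (adjusted p = 0.10 for Eppin and Stard10, 0.17 for Kcnk3).

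At day 13 some macrophage and androgen-responsive transcripts were lower in LuRKO testes. Rhox5, an androgen-regulated homeobox gene of Sertoli cells, was 5.97-fold lower (log2 -2.58, SE 0.47, 2 arrays against 2, limma adjusted p = 0.0026). Insl3 was 5.12-fold lower (log2 -2.36, SE 0.46), and Defb45, a beta-defensin gene, was lower by -2.28 (SE 0.27). Of 13 macrophage markers 7 were lower, 11 adjusted over the list alone, among them C1qb, a complement subunit (-1.07, SE 0.14), and Csf1r, the receptor of a macrophage growth factor (-0.84, SE 0.17). Of 14 androgen-responsive genes 3 were lower, 8 adjusted over the list alone. Camera gave adjusted p = 3.4e-15 for macrophage markers and 1.2e-07 for androgen-responsive genes, and adjusted p = 0.021 and 0.052 with an estimated correlation. Of 7 adult Leydig cell markers 2 were lower, 3 adjusted over the list alone (camera adjusted p = 0.048, adjusted p = 0.15 with an estimated correlation). LuRKO replicate B was doubted for its high Rhox5, an androgen-responsive gene, so leaving it out cannot test that list. Without the doubted arrays androgen-responsive genes had a median of -0.64. Adult Leydig cell markers then had a median of -0.23 and macrophage markers of -0.61, with only LuRKO replicate A left. Insl3 was also nearer to wild type in replicate B alone (-2.04) than in both LuRKO arrays (-2.36). Leaving out replicate B therefore cannot test the Leydig cell markers either. Prm1 was at least 2.27-fold higher in LuRKO testes. Rhox5 was at 9.06 in LuRKO replicate A and 10.61 in B, and was not called without LuRKO replicate A (-1.80) or wild-type replicate B (-2.53). Insl3 was not called without LuRKO replicate A (-2.04), wild-type replicate A (-2.31) or B (-2.41), nor Csf1r without LuRKO replicate A (-0.80) or wild-type replicate A (-0.75). The 95 genes called higher and 168 lower became 142 and 122 when arrays were scaled to 1 median. The count of 263 was 104 without LuRKO replicate A, 43 without wild-type replicate A and 50 without wild-type replicate B of day 13.

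At day 19 the Leydig cell genes Cyp17a1 and Insl3, and most of the androgen-responsive and spermatid lists, were lower in LuRKO testes. Cyp17a1 was 13.4-fold lower (log2 -3.74, SE 0.52), Insl3 11.7-fold, Rhox5 11.4-fold and Drd4, a dopamine receptor gene, 9.25-fold lower (2 arrays against 2, limma adjusted p = 1.1e-05 for Cyp17a1). Of 14 androgen-responsive genes 9 were lower and none higher, and adjusted over the list alone 9 were lower and 1 higher. Spermatid genes were lower in 22 of 30 cases and higher in 1, which was Prm1, at least 2.37-fold higher; adjusted over the list alone 23 were lower. Acrv1, an acrosomal protein gene, was lower by -1.78 (SE 0.23) and Odf1, of the sperm tail, by -1.58 (SE 0.22). Macrophage markers were lower in 9 of 13 cases, 10 adjusted over the list alone with 1 higher, for example Cx3cr1, a chemokine receptor gene (-1.43, SE 0.18). Sertoli cell markers were higher in 7 of 17 cases and lower in 1, and adjusted over the list alone in 9 and 2, led by Gdnf, a growth factor for spermatogonial stem cells (0.99, SE 0.11). Cyp11a1, which starts steroid synthesis, was higher on the probe used (1.01, SE 0.17) and lower on another probe (-1.43, SE 0.21), and the mean of its probes was -0.35, so its direction is open. Star, the cholesterol transport gene, differed by -0.05 (SE 0.14) and was not called. Camera gave adjusted p = 1.0e-04 for androgen-responsive, 5.0e-12 for spermatid, 4.6e-07 for macrophage and 0.0026 for Sertoli cell lists. With an estimated correlation these were adjusted p = 0.15, 0.14, 0.13 and 0.076. By limma 1814 genes were higher and 1697 lower, and the 3511 calls were 2279 without LuRKO replicate A, 2250 without wild-type replicate A and 1669 without wild-type replicate B.

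Among other lists at day 19, adult Leydig cell markers were higher in 1 and lower in 3 of 7 cases, and in 2 and 3 adjusted over the list alone. Vcam1, a cell adhesion gene of that list, was lower by -0.84 (SE 0.15). Steroidogenesis genes were higher in 1 of 11 cases, Cyp11a1, whose direction is open, and lower in 2. Adjusted over the list alone they were higher in 2 and lower in 2. Circadian clock genes were higher in 6 and lower in 1 of 12 cases, as adjusted over the list alone, with Dbp, a clock output gene, higher by 0.74 (SE 0.13). Tight junction genes were higher in 3 and lower in 1 of 12 cases, as adjusted over the list alone, with Ocln, the occludin gene, higher by 0.95 (SE 0.12). Cell cycle genes were higher in 4 and lower in 1 of 19 cases, with 2 lower adjusted over the list alone. Cholesterol biosynthesis and uptake genes were higher in 1 of 16 cases, also adjusted over the list alone. Vitamin A genes were higher in 2 and lower in 1 of 19 cases, and in 1 and 1 adjusted over the list alone. None of the 5 erythroid genes was called by limma, also adjusted over the list alone, with a median above 0 and a mean below 0, and 1 of 5 epididymal and efferent duct markers, Aqp1, a water channel gene, was higher by 0.54 (SE 0.18), and not called with the mean of its probes (0.35) or without LuRKO replicate A (0.38) or wild-type replicate B (0.31). None of these lists reached an adjusted p of 0.05 by camera.

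At day 27 the transcripts of late spermatids were far lower in the 1 LuRKO array than in the 2 wild-type arrays. Cabs1, a gene of elongating spermatids, was 68.2-fold lower (log2 -6.09, SE 0.22, limma adjusted p = 1.7e-19). Oxct2a, the gene of a testis enzyme of ketone body use, was at least 59.7-fold lower. Prm1 was 49.3-fold and Tnp1, the transition protein gene, 41.3-fold lower. All 30 spermatid genes were lower, also adjusted over the list alone (camera adjusted p = 1.6e-27, adjusted p = 0.021 with an estimated correlation). Of 17 Sertoli cell markers 12 were higher and none lower, also adjusted over the list alone, among them Fshr, the receptor of follicle-stimulating hormone (1.92, SE 0.17). Camera gave adjusted p = 0.0029 for this list, and adjusted p = 0.076 with an estimated correlation. The share of Sertoli cells in these testes was not measured here. Wnt5a, a secreted signalling protein gene, was higher by 2.88 (SE 0.27). Aif1, a gene of the macrophage list, was lower by -4.06 (SE 0.20), and in wild-type testes it rose by 4.11 (SE 0.16) from day 3 to day 27. In all 5184 genes were higher and 3162 lower, and the lone array is assumed to vary like those of other groups.

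Averaged over the ages (9 LuRKO against 10 wild-type arrays), Cyp17a1 was lower in LuRKO testes by -2.79 (SE 0.24, limma adjusted p = 2.5e-10), Insl3 by -2.16 (SE 0.22) and Drd4 by -1.80 (SE 0.19). Wnt5a was higher by 1.14 (SE 0.10), Epdr1 by 1.11 (SE 0.08) and Stc1, the stanniocalcin gene, by 1.04 (SE 0.09). Of 17 Sertoli cell markers 13 were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 3.7e-04, adjusted p = 0.041 with an estimated correlation). Of 13 macrophage markers 11 were lower, also adjusted over the list alone (camera adjusted p = 2.6e-06, adjusted p = 0.15 with an estimated correlation). Spermatid genes were lower in 28 of 30 cases, also adjusted over the list alone (camera adjusted p = 2.4e-23, adjusted p = 0.031 with an estimated correlation). Androgen-responsive genes were lower in 8 of 14 cases and higher in 2, also adjusted over the list alone (camera adjusted p = 0.0090, adjusted p = 0.32 with an estimated correlation). With the doubted arrays left out, macrophage markers were lower in 11 cases, 12 adjusted over the list alone (camera adjusted p = 8.5e-07, adjusted p = 0.025 with an estimated correlation). Androgen-responsive genes then had a median of -0.28, but LuRKO day 13 replicate B was doubted for Rhox5, a member of that list. By limma 3816 genes were higher and 3046 lower, and 1961 genes were called over days 8, 13 and 19 alone.

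The effect of testosterone at day 19 was measured against untreated LuRKO testes, and the choice of control moved the counts. The vehicle arrays differed from untreated LuRKO testes in 986 genes called higher and 1137 lower by limma, with Rhox5 higher by 1.64 (SE 0.47) and Drd4 by 1.86 (SE 0.40) in vehicle. The vehicle arrays differed from each other, with Rhox5 at 10.92 in replicate A and 8.15 in replicate B and Insl3 at 12.34 and 9.23. Without vehicle replicate A the differences were 0.25 for Rhox5 and 0.52 for Drd4, not called, and Rhox5 was also not called without untreated replicate A (1.72) or B (1.55). Of 14 androgen-responsive genes 5 were higher in vehicle and of 13 macrophage markers 4, also adjusted over the list alone (camera adjusted p = 0.042 and 0.0039, adjusted p = 0.66 and 0.61 with an estimated correlation). Without the doubted arrays, which left only vehicle replicate B, the lists had medians of 0.15 and 0.023. Vehicle replicate A was doubted for its high androgen-responsive transcripts, so this cannot test that list. The count of 2123 was 1354 without vehicle replicate B and 973 without untreated replicate A. Values against vehicle and against the 4 arrays of 250 ng and 2.5 µg, a control chosen after the values were seen, are therefore also given. Vehicle and low-dose arrays were all taken 24 h after injection, and untreated testes were not injected. At other times effects of the injection itself cannot be told apart from those of testosterone.

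**Figure D2:**
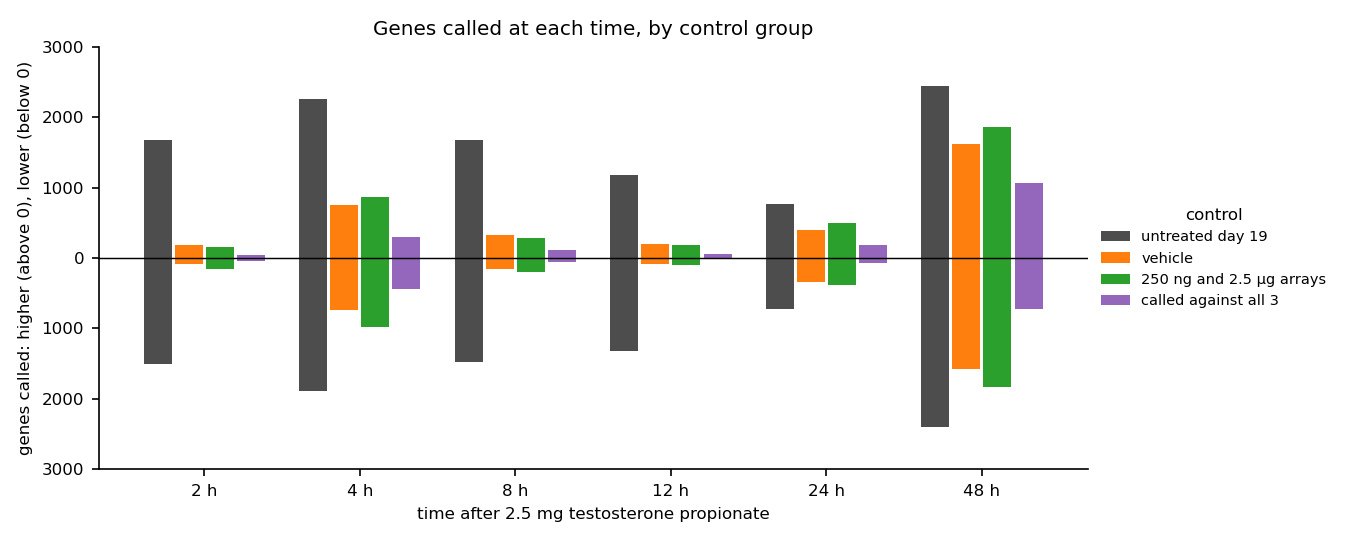
Genes called by limma (y axis, higher above 0 and lower below 0) at each time after 2.5 mg testosterone propionate (x axis), with bars for each control group and for genes called against all 3. At 2 h 1673 genes were higher against untreated testes and 186 against vehicle.

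In the first 8 h Ampd3, an AMP deaminase gene, rose against every control, none of which was a vehicle group of these times. At 2 h it was higher by 0.99 (SE 0.13) against untreated testes, 0.91 (SE 0.13) against vehicle and 0.92 (SE 0.11) against the low-dose arrays, and at 8 h by 2.25, 2.17 and 2.18. Fosl2, an AP-1 transcription factor gene, was higher at 4 h by 1.24 (SE 0.15), 1.24 (SE 0.15) and 0.95 (SE 0.13). Pdk4, a kinase gene of fuel metabolism, was higher at 4 h by 0.86, 0.76 and 0.76, and Fkbp5, a steroid receptor co-chaperone gene, by 0.72, 0.54 and 0.47. All these differences were called by limma (2 arrays in each treated group). Stc1 fell at 4 h, by -0.84 (SE 0.20), -1.47 (SE 0.20) and -1.30 (SE 0.17), and against untreated testes it was not called without 4 h replicate A (-0.53). Of 11 targets shared by the glucocorticoid and androgen receptors 5 were higher at 4 h against untreated testes and none lower, also adjusted over the list alone. Camera gave adjusted p = 0.044 for that list, and adjusted p = 0.53 with an estimated correlation. Against vehicle 4 were higher, 5 adjusted over the list alone (camera adjusted p = 0.038, adjusted p = 0.60 with an estimated correlation). Against the low-dose arrays 5 were higher, also adjusted over the list alone (camera adjusted p = 0.0069, adjusted p = 0.42 with an estimated correlation). Lists of other cell types moved at 4 h too. Against untreated testes spermatid genes were lower in 9 of 30 cases, also adjusted over the list alone (camera adjusted p = 0.0022, adjusted p = 0.62 with an estimated correlation). Against vehicle 1 of 16 matrix genes was higher, 3 adjusted over the list alone, and 2 of 13 macrophage markers were lower, 5 adjusted over the list alone (camera adjusted p = 0.045 and 0.038, adjusted p = 0.63 for each with an estimated correlation). Low-dose arrays as control gave 5 matrix genes and 3 of 12 endothelial markers higher, 8 and 4 adjusted over the list alone (camera adjusted p = 0.0035 and 0.021, adjusted p = 0.42 for each with an estimated correlation). There 4 spermatid and 5 of 25 meiotic genes were lower, and adjusted over the list alone 8 spermatid and 6 meiotic genes were lower and 1 meiotic gene higher (camera adjusted p = 0.0098 and 0.018, adjusted p = 0.61 and 0.42 with an estimated correlation). Immediate early genes were higher at 4 h in 5 of 17 cases against untreated testes, and adjusted over the list alone in 5 with 1 lower. They were higher in 2 against vehicle and 3 against the low-dose arrays, also adjusted over the list alone, and camera did not call the list (adjusted p = 0.11, 0.14 and 0.12). At 8 h 7 immediate early genes were higher and 1 lower against untreated testes, also adjusted over the list alone (camera adjusted p = 0.035, adjusted p = 0.53 with an estimated correlation). Against vehicle 4 were higher at 8 h, 5 adjusted over the list alone (camera adjusted p = 0.038, adjusted p = 0.60 with an estimated correlation). Against the low-dose arrays 4 were higher, and adjusted over the list alone 6 with 1 lower (camera adjusted p = 0.016, adjusted p = 0.42 with an estimated correlation). Spermatid genes at 8 h were lower in 7 and higher in 1 of 30 cases against untreated testes, 8 and 1 adjusted over the list alone (camera adjusted p = 0.0045, adjusted p = 0.66 with an estimated correlation). Against vehicle 1 macrophage marker was lower at 8 h, 4 adjusted over the list alone (camera adjusted p = 0.043, adjusted p = 0.63 with an estimated correlation). Against the 2 h group, itself treated, Fosl2, Pdk4, Fkbp5 and Stc1 were not called at 4 h.

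Genes called higher and lower against untreated testes were 1673 and 1503 at 2 h, 2261 and 1886 at 4 h and 1683 and 1476 at 8 h. Against all 3 controls they were 45 and 39 at 2 h, 305 and 443 at 4 h and 116 and 51 at 8 h. Cldn23, a claudin gene, was higher at 2 h by 2.72 (SE 0.30) against untreated testes, and by 0.54 (SE 0.30) against vehicle, where it was not called. The 2 h count of 3176 was 1746 without 2 h replicate B and 2055 without untreated replicate A. The 4 h count of 4147 was 2117 without 4 h replicate B. The 8 h count of 3159 was 1620 without 8 h replicate A and 2027 without untreated replicate A.

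**Figure D3:**
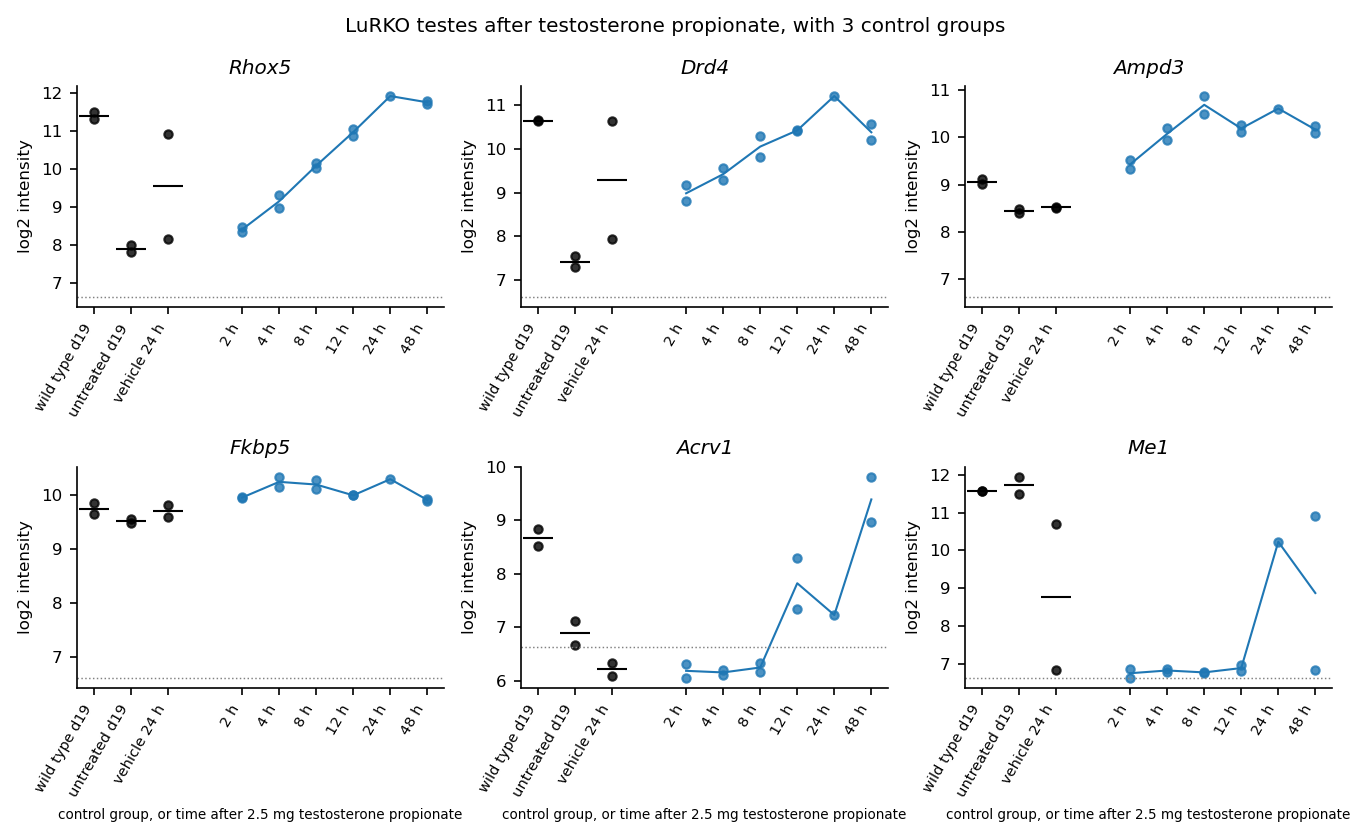
Log2 intensity (y axes) of 6 transcripts in day 19 wild-type, untreated LuRKO and vehicle testes (black points, with a bar at the mean) and at 2 to 48 h after 2.5 mg testosterone propionate (blue points, line through means), with the background threshold dotted. Rhox5 averaged 7.90 in untreated LuRKO and 11.75 at 48 h.

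At 12 h Acrv1 and Gtsf1l were higher than in every control. Acrv1 was higher by 0.93 (SE 0.23) against untreated testes and 1.41 (SE 0.20) against the low-dose arrays, and was also called by limma against vehicle, where it was not above background (2 arrays at 12 h). Gtsf1l was higher by 0.84, 1.93 and 1.68, also called against each. Against untreated testes it was not called with only the arrays of the same series (limma adjusted p = 0.051) or an offset of 16 (adjusted p = 0.077). Rhox5 was higher by 3.07 (SE 0.47) against untreated testes and 2.70 (SE 0.41) against the low-dose arrays, and by 1.43 (SE 0.47, limma adjusted p = 0.12) against vehicle. Of 12 circadian clock genes 5 were lower against the low-dose arrays, 6 adjusted over the list alone (camera adjusted p = 8.6e-07, adjusted p = 0.016 with an estimated correlation), among them Dbp (-0.73, SE 0.11). Against vehicle 2 were lower, 3 adjusted over the list alone (camera adjusted p = 0.0076, adjusted p = 0.21 with an estimated correlation). Spermatid genes were higher in 6 of 30 cases against vehicle and against the low-dose arrays, 17 and 13 adjusted over the list alone (camera adjusted p = 1.2e-11 and 6.5e-11, adjusted p = 0.31 and 0.28 with an estimated correlation). Macrophage markers were lower in 2 of 13 cases against vehicle, 3 adjusted over the list alone (camera adjusted p = 0.032, adjusted p = 0.63 with an estimated correlation). Nr1d1, a nuclear receptor of the clock, was not above background at 12 h and at least 1.42-fold lower than in untreated testes. Against untreated testes, Acrv1 and Gtsf1l were not called without 12 h replicate A (0.45 and 0.39) or untreated replicate B (0.70 and 0.76), nor Nr1d1 without 12 h replicate B (fitted log2 -0.53) or untreated replicate A (-0.49). Against untreated testes 4 clock genes were lower, 5 adjusted over the list alone (camera adjusted p = 0.088). Vehicle and low-dose arrays were all taken 24 h after injection. Time of day at sampling was not analysed here, so for clock genes at 12 h it cannot be told apart from a response to testosterone. Against untreated testes 1175 genes were higher and 1327 lower, and 55 and 19 against all 3 controls. The count of 2502 was 1525 without 12 h replicate A, 1391 without 12 h replicate B and 1545 without untreated replicate A.

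At 24 h the 1 array of 2.5 mg had higher Rhox5 and Drd4 than every control. Rhox5 was higher by 4.02 (SE 0.57) against untreated testes, 2.38 (SE 0.57) against vehicle and 3.65 (SE 0.52) against the low-dose arrays, and Drd4 by 3.77, 1.90 and 2.68. Defb45 was higher by 2.37, 1.64 and 2.16, and Ifi27l2a, an interferon-induced gene, by 3.82, 2.49 and 3.33. Pappa, a protease gene that acts on insulin-like growth factor binding proteins, was lower by -1.47, -1.35 and -1.28. Each of these was called by limma against all 3 controls. Against untreated testes 5 of 14 androgen-responsive genes were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.0045, adjusted p = 0.50 with an estimated correlation). Against vehicle 3 were higher and 1 lower, also adjusted over the list alone, and camera did not call the list (adjusted p = 0.15). With the doubted arrays left out, the list had a median of 0.36 against the 1 vehicle array left. Vehicle replicate A was doubted for its high androgen-responsive transcripts, so this cannot test the list. Against the low-dose arrays 4 were higher and 1 lower, and 6 and 1 adjusted over the list alone (camera adjusted p = 0.0035, adjusted p = 0.42 with an estimated correlation). Immediate early genes were higher in 6 of 17 cases against untreated testes, 7 adjusted over the list alone (camera adjusted p = 0.011, adjusted p = 0.50 with an estimated correlation). They were higher in 2 against vehicle and 4 against the low-dose arrays, and adjusted over the list alone in 4 with 1 lower against each (camera adjusted p = 0.045 and 0.039, adjusted p = 0.63 and 0.42 with an estimated correlation). With the doubted arrays left out, 1 was higher than in vehicle, and adjusted over the list alone 4 were higher and 3 lower (camera adjusted p = 0.38). Macrophage markers were higher in 4 of 13 cases and lower in 1 against untreated testes, 5 and 1 adjusted over the list alone, and higher in 4 against the low-dose arrays, with 1 lower adjusted over the list alone (camera adjusted p = 0.0045 and 0.0035, adjusted p = 0.53 and 0.42 with an estimated correlation). The 774 genes higher and 718 lower against untreated testes became 626 and 909 with arrays scaled to 1 median, and 179 and 77 genes were called against all 3 controls.

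At 48 h spermatid genes rose against vehicle in 26 of 30 cases and none fell, also adjusted over the list alone, with a median of 1.40. Camera gave adjusted p = 5.5e-31 for this list, and adjusted p = 0.0042 with an estimated correlation. Acrv1 was at least 6.80-fold higher than in vehicle and higher by 2.50 (SE 0.23) against untreated testes, and Tnp1 by 0.65 (SE 0.20) against vehicle but by 0.37 against untreated testes, where it was not called. Sertoli cell markers fell in 9 of 17 cases, also adjusted over the list alone (camera adjusted p = 3.6e-05, adjusted p = 0.0056 with an estimated correlation), among them Gdnf by -0.80 (SE 0.11). Spermatogonial markers fell in 8 of 21 cases, also adjusted over the list alone (camera adjusted p = 4.8e-04, adjusted p = 0.38 with an estimated correlation), among them Kit, a receptor of differentiating spermatogonia (-0.67, SE 0.20), and Stra8, a gene of meiotic entry (-1.16, SE 0.27). Against the low-dose arrays 26 spermatid genes were higher, 27 adjusted over the list alone (camera adjusted p = 3.4e-30, adjusted p = 0.017 with an estimated correlation). Sertoli cell markers were lower there in 7 cases, 8 adjusted over the list alone (camera adjusted p = 7.0e-04, adjusted p = 0.070 with an estimated correlation). Against untreated testes Sertoli cell markers were higher in 2 cases and lower in 8, 3 and 8 adjusted over the list alone, and camera did not call the list (adjusted p = 0.059). Against vehicle 1615 genes were higher and 1584 lower by limma, against untreated testes 2443 and 2397, against the low-dose arrays 1867 and 1831, and against all 3 controls 1065 and 727. Against vehicle, Tnp1 was not called without 48 h replicate B (0.12), vehicle replicate A (0.61) or B (0.69), Kit without 48 h replicate A (-0.66) or B (-0.68) or vehicle replicate B (-0.52), and Stra8 without vehicle replicate B (-0.84). Of 14 androgen-responsive genes 2 were higher and 1 lower against vehicle, 3 and 1 adjusted over the list alone (camera adjusted p = 0.17). Vehicle replicate A was doubted for its high androgen-responsive transcripts, so leaving it out cannot test this list. Without the doubted arrays these 14 genes had a median of 0.28. Spermatogonial markers then had a median of -0.53 against vehicle replicate B alone. Testes at 48 h were 24 h older than those of vehicle.

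The rescue comparison asks which transcripts changed by loss of the receptor move back with testosterone. Of 1697 genes lower in LuRKO than wild-type testes at day 19, 841 were higher and 35 lower at 48 h than in vehicle, where independent lists would give 180 and 177. Of 1814 genes higher in LuRKO testes, 663 were lower and 13 higher, where independent lists would give 189 and 193. Testes at 48 h were 24 h older than those of vehicle, and with the 1 array of 24 h, of the same age as vehicle, the 841 and 663 were 72 and 53. Among genes lower in LuRKO, Gtsf1l rose by 3.50 (SE 0.24), Ssty2, a Y-linked spermatid gene, by 3.41 (SE 0.35) and Ankrd61 by 3.37 (SE 0.29), with Spata45 at least 7.97-fold and Dnajc5b at least 7.74-fold higher. Among genes higher in LuRKO, Pappa fell by 1.47 (SE 0.15), Dkk3, a secreted Wnt pathway gene, by 1.41 (SE 0.19) and Bcan, a proteoglycan gene, by 1.39 (SE 0.25). Of these 8 genes Pappa and Dkk3 were also called at 24 h against vehicle (-1.35 and -0.88). Across genes the 48 h effect against vehicle had r = -0.62 with the genotype difference at day 19. Against untreated testes, which both differences share, r was -0.68 and covariance -0.121, while simulated groups with no effect gave -0.50 and -0.0119. Genes are not independent replicates, and part of the latter correlation may come from the shared control. The 841 were 461 without vehicle replicate B, 530 without untreated replicate B and 398 without wild-type replicate B, and the 663 were 187 without vehicle replicate B, 324 and 346 without 48 h replicates A and B, and 361 without wild-type replicate B.

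The dose series asks how the response at 24 h depends on dose. Ampd3 was at 8.56 at 250 ng and 8.46 at 2.5 µg, close to 8.52 in vehicle, and higher by 1.06 (SE 0.13, limma adjusted p = 2.7e-05) at 25 µg and by 2.09 (SE 0.16) at 2.5 mg. Rhox5 at 25 µg was higher by 1.46 (SE 0.47, adjusted p = 0.16) against vehicle, and by 2.73 (SE 0.41, adjusted p = 7.0e-04) against the 4 low-dose arrays by limma. Drd4 had 1.26 (SE 0.40) and 2.04 (SE 0.34), called against the low-dose arrays. Without vehicle replicate A, doubted for high transcripts of this kind, the differences against vehicle were 2.84 for Rhox5 and 2.60 for Drd4. Of 14 androgen-responsive genes none was called at 25 µg against vehicle, with 2 higher adjusted over the list alone (camera adjusted p = 0.22). Without the doubted arrays these 14 genes had a median of 0.22, which cannot test the list, as vehicle replicate A was doubted for such genes. Against the low-dose arrays 3 were higher at 25 µg, 5 adjusted over the list alone (camera adjusted p = 6.0e-05, adjusted p = 0.25 with an estimated correlation). At 250 ng none was called against vehicle, with 4 lower adjusted over the list alone (camera adjusted p = 0.0035, adjusted p = 0.46 with an estimated correlation). Without the doubted arrays the list had a median of 0.012 at 250 ng, which again cannot test it. Macrophage markers were lower than in vehicle in 1 of 13 cases at 250 ng and none at 2.5 or 25 µg, and adjusted over the list alone in 4, 7 and 1 (camera adjusted p = 2.2e-04, 2.9e-05 and 0.014, adjusted p = 0.46, 0.39 and 0.66 with an estimated correlation). Camera did not call them at these doses without the doubted arrays (adjusted p = 0.80, 0.61 and 0.94). Trim30a, an interferon-induced gene, was at least 3.19-fold higher at 2.5 mg than in vehicle, and Ctsl, a lysosomal protease gene, was lower by -1.72 (SE 0.32). Ampd3 also had the smallest p for the slope from 250 ng to 25 µg, at 0.51 (SE 0.06) for each step of 10-fold, followed by Syt7, a synaptotagmin gene (0.41, SE 0.06), and Clstn1 (0.66, SE 0.10), neither called without 25 µg replicate B (0.35 and 0.60).

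Genes called by limma against vehicle numbered 5 higher and 4 lower at 250 ng, 4 and 4 at 2.5 µg, 54 and 15 at 25 µg, and 396 and 335 at 2.5 mg, with 43 rising and 5 falling along the slope. Against the low-dose arrays 25 µg gave 47 and 4, of which 11 and 2 were shared, and 2.5 mg gave 492 and 384. Taf15, an RNA-binding protein gene, and Dus4l were higher than vehicle at 250 ng, by 1.46 (SE 0.20) and 1.03 (SE 0.11), and Taf15 was not called without 250 ng replicate A (1.33). At 250 ng the 9 calls were 2 and 3 without its replicates A and B, and 3 and 63 without vehicle replicates A and B. At 2.5 µg the 8 calls were 5 and 24 without its replicates, and 5 and 76 without those of vehicle. At 25 µg the 69 calls were 4 and 20 without its replicates A and B and 37 without vehicle replicate B. At 2.5 mg the 731 calls were 433 and 321 without vehicle replicates A and B. The 48 slope calls were 28 and 6 without 25 µg replicates A and B, and 24 and 28 without those of 250 ng.

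**Figure D4:**
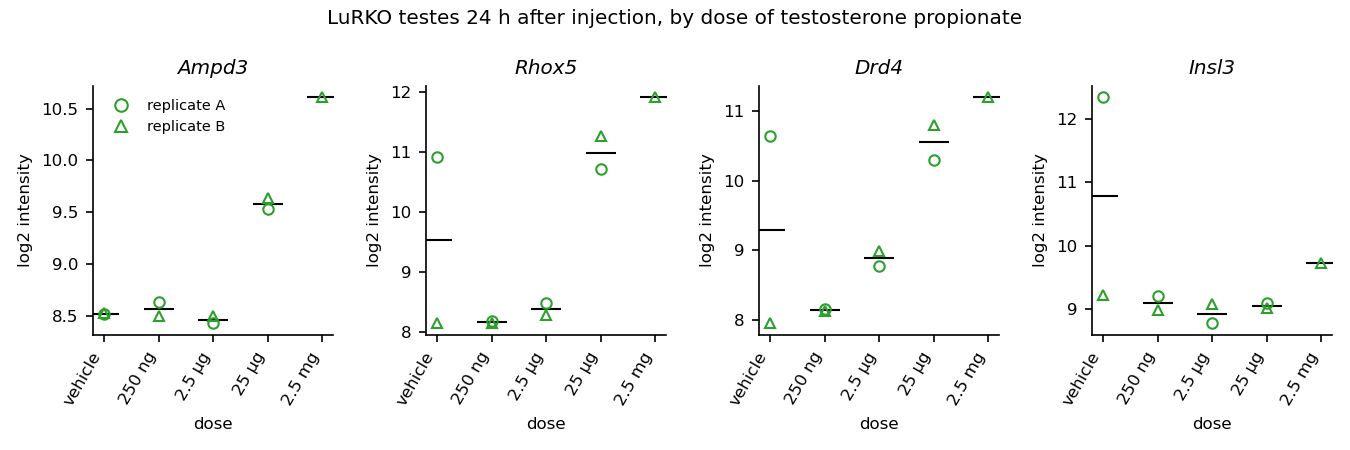
Log2 intensity (y axes) of 4 transcripts at 24 h by dose of testosterone propionate (x axes), with replicate A as circles, replicate B as triangles and bars at the means. Vehicle replicate A lies at 12.34 for Insl3 and vehicle replicate B at 9.23.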

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

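The interaction over 3 ages alone was chosen only after the results were seen. The genotype difference changed with age in 7739 genes by limma's test of the interaction, over 9 LuRKO and 10 wild-type arrays. The smallest p-values belonged to Prss55 (adjusted p = 3.6e-20), Trp53tg5 (2.1e-19) and Iqcf1 (2.1e-19) by limma. At day 27 Iqcf1 was lower by -5.36 (SE 0.14), Prss55 at least 30.1-fold and Trp53tg5 at least 30.3-fold in the 1 LuRKO array, and none of the 3 was called at days 3, 8, 13 or 19. Over days 8, 13 and 19 alone 1004 genes were called.

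Arrays were split within ages in 100 ways, the real one included. For the interaction 3 splits gave as many genes as the real 7739, with 8411 in the highest other, which argues against a chance split at the 0.05 level. Splits within ages remove any genotype effect, also one that is equal at all ages. They therefore cannot test whether the effect changes with age. For the average genotype difference 1 split, the real one, gave 6862 genes, with 6208 in the highest other, which also argues against a chance split. Traits of the 1 LuRKO array of day 27, or of a set of arrays, cannot be excluded by these splits as a source of the calls.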

How the results depend on the processing

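The 2 h and low-dose controls, the offset of 16, the 3 ages alone and the 3 doubted arrays were chosen only after the results were seen. Of 344 alternative counts 270 were within 1.5 times the main count and 74 were not. Of 1488 values of named genes under alternatives, 1397 kept their side of the threshold, and their direction where called. Of the others 79 lost and 10 gained a call, and 2 reversed. The reversals were Cyp11a1 at day 19, at -0.35 with the mean of its probes, which disagree, and Tnp1, at -0.18 with 24 h in place of 48 h. The authors' values without background correction, no detection filter and a filter on every array of a group kept all 23 counts within 1.5 times. Where a count moved, the cause was not tested.

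Against vehicle the counts from 2 to 48 h were 270, 1491, 491, 290, 731 and 3199, and against the low-dose arrays 302, 1839, 482, 284 and 876 from 2 to 24 h. Against the 2 h group 4, 8 and 12 h gave 5, 25 and 236. With 24 h in place of 48 h the rescue gave 72 and 53. At day 8 the count was 0 with scaling to 1 median, 4 with the mean of probes, 13 with arrays of 1 series and 0 with an offset of 16, against 7 by limma and 1268 at an unadjusted p under 0.05. At day 13 it was 162 with an offset of 16. With the mean of probes 250 ng gave 5, and with arrays of 1 series 250 ng gave 2, 25 µg 21 and the slope 22. Without the 3 doubted arrays 25 µg gave 105. They were vehicle replicate A, LuRKO day 13 replicate B, with Rhox5 at 10.61 (9.06 in A), and wild-type day 3 replicate A, with Ldhc at 10.61 (7.70 in B). Over days 8, 13 and 19 the average gave 1961 and the interaction 1004. With an estimated correlation 14 list tests were called.

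Leaving out 1 array at a time, counts ranged from 1746 to 2475 at 2 h, 2117 to 3618 at 4 h, 1620 to 2523 at 8 h, 1391 to 2136 at 12 h, 1187 to 1202 at 24 h and 3268 to 4091 at 48 h. They ranged from 2 to 63 at 250 ng, 5 to 76 at 2.5 µg, 4 to 48 at 25 µg, 321 to 433 at 2.5 mg, 6 to 28 for the slope and 973 to 2120 for vehicle against untreated. For the rescue they were 398 to 860 and 187 to 655. For genotype they were 708 to 1264 at day 3, 0 to 1 at day 8, 43 to 186 at day 13, 1669 to 2652 at day 19, 7563 to 7631 at day 27, 6473 to 6854 for the average and 7197 to 8008 for the interaction. For development they were 10526 to 10641 in wild-type and 8304 to 8467 in LuRKO testes. Groups left with 1 array are assumed to vary like the others.

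Replicate letters did not pair the arrays: over 153 pairs of groups the correlation of A minus B ranged from -0.26 to 0.25, with 23 over 0.1. With the letter as a replicate block all 23 counts stayed within 1.5 times, with 3510 called at day 19 where 3511 were called without it. Slide as a block was not run, since the files used give no slides. Signal over background limits genes near 6.62 (log2), which have only bounds.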

Other observations

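All tests of explanations in this part were chosen only after the results were seen, and those on the genes lower at 2 h and on age at 48 h were changed after their values were seen. Germ cell transcripts also rose with age in LuRKO testes, to a smaller extent for spermatid genes. From day 3 to day 27 (1 array against 2) 28 of 30 spermatid genes rose, also adjusted over the list alone, with a median of 1.97 where wild-type testes had 6.33 (limma's camera adjusted p = 8.5e-12, adjusted p = 0.054 with an estimated correlation). Meiotic prophase genes rose in 24 of 25 cases, also adjusted over the list alone (camera adjusted p = 4.7e-18, adjusted p = 3.2e-04 with an estimated correlation). Ldhc rose by 7.05 (SE 0.49) and Adam3 at least 83.4-fold. Spink2, which the list of androgen-responsive Sertoli cell genes holds, rose by 6.84 (SE 0.26). Hsd17b3, the enzyme of the last step of testosterone synthesis, fell at least 27.7-fold, Cyp17a1 fell by 2.81 (SE 0.63) and Insl3 fell by 2.32 (SE 0.57).

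At day 27 spermatogonial markers were higher in 13 of 21 cases in the 1 LuRKO array and lower in 1, also adjusted over the list alone, with limma's camera adjusted p = 0.12 and adjusted p = 0.72 with an estimated correlation. Dazl, an RNA-binding protein gene of germ cells, was higher by 2.33 (SE 0.19) and Kit by 1.22 (SE 0.25). Prm1, a late spermatid gene, differed by 1.34 (SE 0.17) at day 3 and 0.58 at day 8, the latter not called, and was at least 2.27-fold higher at day 13 and 2.37-fold at day 19 in LuRKO testes. Another Prm1 probe differed by 1.37 (SE 0.18) at day 3. Over LuRKO testes of days 3 and 8, 15 other genes bright in wild type at day 27 and below background there at day 13 had a median of 0.067 of the rise in proportion to that of Prm1, and 0 reached 0.5 of it.

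The first pattern is the set of 426 genes at least 2-fold lower at 2 h than in untreated testes, with a median of -1.36. Against wild-type day 19 testes, whose arrays had no part in choosing these genes, vehicle had a median of -1.01 (quartiles -1.42 and -0.67), with -0.96 in replicate A and -1.06 in B, 2 h had -1.33, and wild type itself had -0.07 against untreated LuRKO testes, which argues against a response to testosterone given or made in the tissue. The 65 other bright probes of 51 of these genes had a median of -0.14, where the probes used had -1.37, which argues against a change in transcript level. Uninjected LuRKO testes had medians against wild type of -0.80 at day 3, -0.05 at day 8, -0.02 at day 13, 0.07 at day 19 and 0.66 at day 27. A difference between sets of arrays that acts on single probes therefore stays open, as the files used give no set, although 153 of the 197 genes at least 2-fold lower in LuRKO at day 3 were among the 426.

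The second pattern is vehicle replicate A, with Cyp17a1 at 10.91 and Insl3 at 12.34 where replicate B had 7.43 and 9.23. An array of a testosterone-treated testis is argued against, since both genes lay at least 1.90 above every treated array. Tissue with a working receptor as advanced as wild type at day 19 is argued against by 9 spermatid genes, which lay a median fraction of -0.036 of the way to wild type, with an upper quartile of -0.0084, where 8 Leydig and androgen-responsive genes had a lower quartile of 0.503. Tissue with a working receptor from a less advanced testis stays open. Those 8 genes had a median fraction of 0.671, but genes of these kinds drew attention to the array, so this cannot test it. That explanation cannot be told apart from differences between animals with 1 array, whose age label is also later than its time after injection.

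The third pattern is the change from vehicle to 48 h, where age differs by 24 h. Across 15194 genes, which are not independent replicates, it had r = 0.518 (rho = 0.449) with the change of wild-type testes from day 19 to day 27, r = 0.305 with that of untreated LuRKO testes and r = 0.623 with wild type minus LuRKO at day 19, and 24 h against vehicle had r = 0.043 with the first. At 12 h, in testes 12 h younger than vehicle, 6 of 30 spermatid genes were higher and none lower, 17 adjusted over the list alone, with a median of 0.43 (camera p = 0.0099 with an estimated correlation, adjusted p = 0.31), a direction opposite to that of age, and at 24 h the median was 0.24 (p = 0.23). Without the doubted arrays spermatid genes had a median of -0.23 in vehicle against untreated testes, so a low level in vehicle may enter the 12 h difference. The 26 spermatid genes called at 48 h had a median of 1.54 there and 1.54 over the 8 days from day 19 to day 27 in untreated LuRKO testes, with quartiles of 1.02 to 1.76 and 0.74 to 2.04, and 16 of them rose more at 48 h. The extra day and the response to testosterone cannot be told apart at 48 h, since 8 days do not measure 1 day and no vehicle array of 48 h was analysed here.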
